A study of Homo sapiens with 18 samples.

How the data were processed

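The data are 18 RNA-seq libraries of MDA-MB-231 spheroids in 6 groups of 3, from 2 genotypes and 3 conditions. Per the labels' protocols, spheroids were formed for 5 days in hanging droplets and sampled there or after 24 h or 48 h in collagen, and polyA libraries were sequenced as 151 bp pairs. Per the submitters' processing notes, reads were handled with cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3 and MultiQC 1.7 on GRCh38, and DESeq2 1.42.0 is also listed. The deposited table holds expected counts per gene from RSEM, and every value in it was already a whole number. The annotation release and the strand setting of the counting are not given in the sources used here. The table has 62714 rows, of which 4 reporter sequences with a count of 0 in every library were left out. Of the remaining 62710 genes, 20930 had no symbol in the table, 58274 were matched by identifier to GENCODE 29 for coordinates, gene class and overlaps, and 29346 had no read in any library. Groups were assigned from the genotype and treatment labels.

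Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr on the 6 groups (minimum count 10), which kept 17030, and libraries were scaled by TMM. A single model with 1 coefficient per group was fitted to the 18 libraries with robust quasi-likelihood estimation (12 residual degrees of freedom, common dispersion 0.00481). The 13 contrasts were targeted against control in each condition and averaged over the 3, each pair of conditions within a genotype, and 3 interactions. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05, and counts at an absolute log2 fold change of 1 or more are given beside the totals. The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. Levels are CPM with the TMM factors, as mean and SD over 3 libraries. With total counts of 19819401 to 33352163 per library, the floor of a single read lies well under the 5 CPM asked of named genes.

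Named genes follow a rule fixed before the data were examined. MMP14 was always named. In the genotype contrasts and in the control contrasts of collagen with droplets the rule takes the 8 largest rises and falls among genes that passed, had a mean of at least 5 CPM in the higher group, did not overlap between the groups compared and carried a gene symbol that is not a clone or locus name. In each interaction it takes the 8 smallest adjusted p with the same limits on level and symbol, and in the other contrasts the 4 largest rises and falls. Members of gene lists were named by absolute log2 fold change, up to 4 per list among those that passed with at least 1 CPM. A gene named in 1 contrast could be given its values in another, and not every gene the rule takes is printed.

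The 35 gene lists were written from general knowledge before the data were examined. The result of 1 list is not reported. The others cover matrix metalloproteinases, other pericellular and lysosomal proteases, protease inhibitors, collagens and matrix proteins, collagen crosslinking and processing, integrins, focal adhesion and invadopodium, Rac-Cdc42 protrusion, mesenchymal transition, epithelial genes, YAP-TAZ targets, MRTF-SRF targets, TGF-beta targets, hypoxia, glycolysis, DNA replication, mitosis, p53 targets, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory cytokines, immediate-early and dissociation genes, heat shock, the unfolded protein response, ATF4 targets, cholesterol synthesis, oxidative phosphorylation, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, and markers of luminal breast epithelium, fibroblasts, leukocytes and endothelium. Together the 35 hold 1043 different genes, and some genes are in more than 1 list. Lists with at least 5 tested members were tested with camera on the edgeR fit with an inter-gene correlation preset at 0.01, adjusted over the lists within a contrast. The tests were repeated with an estimated correlation, and with fry, which asks whether the members of a list move one way on balance and does not compare the list with other genes.

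The scripts were tested on simulated counts for the comparison of targeted with control spheroids at 24 h, drawn from the mean levels, gene-wise dispersions and library sizes of the real samples. Of these, 16709 genes passed the filter, and the changed genes were taken from those above a minimum expected count. At a fold change of 1.5, 53 of 67 changed genes were recovered (79.1%), at 2, 60 of 67 (89.6%), and at 4, 66 of 66. Of 16469 unchanged genes 11 were called, which is 4.89% of the 225 calls. The 1 list that was shifted was called with both correlations, and 0 of 34 unshifted lists were called with the preset one. Genes were drawn independently of each other, so the simulation cannot show how the list tests behave when members are correlated. In a simulated droplet comparison with nothing changed, 1 of 16709 genes was called.

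Alternatives tried were DESeq2's size factors in edgeR, library size alone, no filter, a stricter filter (at least 3 libraries with 1 CPM or more), the replicate number as a block, mitochondrial genes left out, no robust estimation, DESeq2 1.42.0, limma-voom, a fit with only the groups compared, collagen-response sets at 4-fold in place of 2-fold, each library left out in turn, and, chosen after the data were seen, only genes with a mean of at least 10 CPM. Chi-square per degree of freedom between replicates was 2.9 to 13.3 (a check for copied libraries, whose value would be 0). Other splits of the libraries were refitted with the same model, all 10 for each pair of groups and 60 draws that reassign genotype labels within conditions for the averaged contrast and each interaction. All columns of the table were used, and the labels give no sequencing batch or date.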

Results

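Gene expression was measured by sequencing polyA-selected RNA, as 151 bp read pairs, in spheroids of MDA-MB-231, an established triple-negative breast cancer cell line. The 18 libraries form 6 groups of 3. Control spheroids and MMP14-targeted spheroids were each sampled in hanging droplets after 5 days of formation, or after 24 h or 48 h inside a collagen hydrogel. MMP14 encodes a membrane-anchored metalloproteinase that cleaves fibrillar collagen. Each sample held 100000 cells in spheroids of 2000 cells. Spheroids in collagen were recovered by digestion with collagenase at 2 mg/ml and 37 °C, and spheroids in droplets were not digested. Total counts per library ranged from 19819401 to 33352163. The group means were 25.3 ± 3.46 M counts (SD, n = 3) in control droplets, 27.8 ± 4.90 M in control at 24 h and 24.9 ± 1.27 M in control at 48 h. They were 27.4 ± 2.19 M in targeted droplets, 23.6 ± 1.96 M in targeted at 24 h and 22.2 ± 3.10 M in targeted at 48 h. The 17030 genes tested held at least 99.924% of the counts of every library. The labels do not state whether the replicates of a group are separate cultures.

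Libraries separated by genotype, and droplet libraries from those in collagen, while 24 h and 48 h libraries of a genotype lay together. In a principal component analysis of the 500 most variable tested genes, the first component held 33.5% of the variance, the second 22.8% and the third 4.32%. The 3 targeted droplet libraries had first-component scores of -31.5 to -29.9, and the 3 control droplet libraries had scores of -2.10 to -0.00241. Across genes, the correlation of log2 CPM between libraries was 0.987 to 0.991 within groups and 0.952 to 0.988 between groups.

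**Figure D1:**
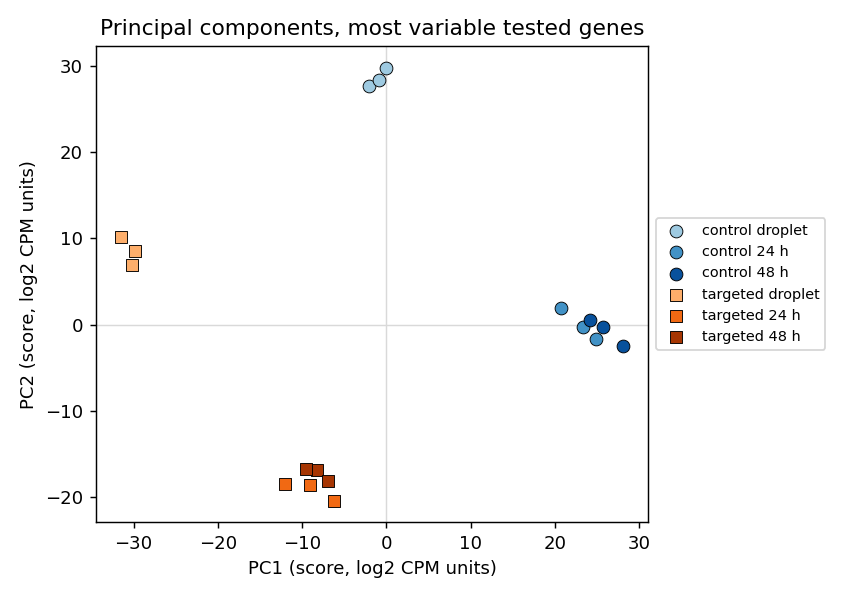
First against second principal component score of each of the 18 libraries, from log2 CPM of the 500 most variable tested genes; circles are control libraries, squares are MMP14-targeted libraries, and darker colours are longer times in collagen. Within each genotype the 24 h and 48 h libraries lie together and apart from the droplet libraries, and the genotypes lie apart on the first component, which holds 33.5% of the variance.

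MMP14 mRNA was lower in all 9 targeted libraries than in all 9 control libraries. The gene lies on chromosome 14 at 22836557 to 22849027 (GRCh38, plus strand). Control libraries held 1284 to 2250 CPM and targeted libraries held 137.9 to 165.6 CPM. In droplets the mean was 2045 ± 178 CPM in control and 154.5 ± 5.20 CPM in targeted spheroids (SD, n = 3 each), a log2 fold change of -3.73 (SE 0.0903, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.12e-16) that left 7.55% of the control level. At 24 h the means were 1819 ± 139 and 153.2 ± 11.6 CPM (8.42% of control), and at 48 h they were 1447 ± 143 and 147.9 ± 13.4 CPM (10.2% of control). MMP14 fell in control spheroids between 24 h and 48 h (log2 fold change -0.33, SE 0.0807, adjusted p = 0.00918 by the same test). Transcript level does not show whether the remaining mRNA encodes protein.

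**Figure D2:**
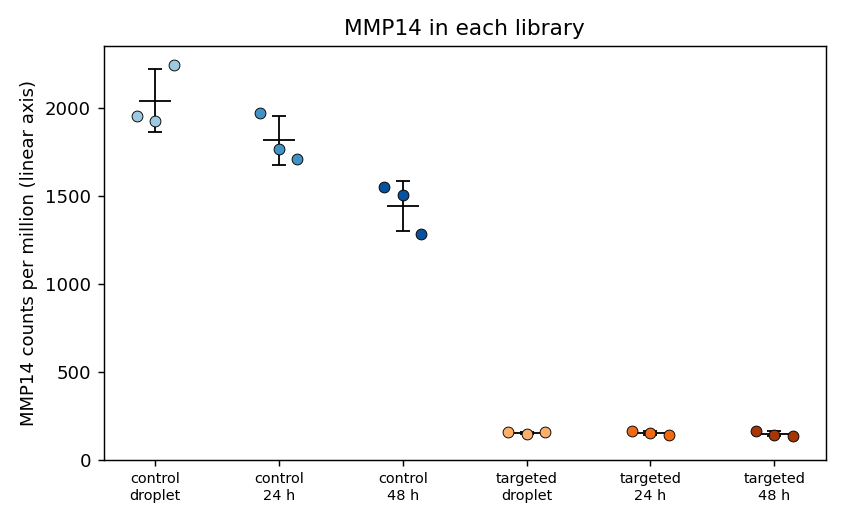
MMP14 CPM of each library on a linear axis; points are libraries, the long horizontal mark is the group mean and the whiskers are 1 SD (n = 3). The 9 targeted libraries lie between 137.9 and 165.6 CPM, all below the lowest control library at 1284 CPM.

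The response of control spheroids to collagen was measured by comparing embedded with droplet spheroids. Immediate-early genes and targets of the mechanically regulated coactivators YAP and TAZ rose, while interferon-stimulated genes fell. DNA replication genes also rose and antigen presentation genes fell, but these list calls were lost with an estimated correlation (adjusted p = 0.0639 and 0.111 at 24 h and 0.163 and 0.0681 at 48 h by camera on the edgeR fit). FOS, an AP-1 transcription factor subunit, rose from 6.46 ± 0.996 CPM in droplets to 929.3 ± 95.3 CPM at 24 h and stood at 480.2 ± 36.2 CPM at 48 h (SD, n = 3 each). CCN2, a secreted YAP target, rose from 85.0 ± 2.43 to 881.1 ± 52.5 and 719.9 ± 69.9 CPM. CXCL10, an interferon-induced chemokine, was at 22.2 ± 3.65 CPM in droplets and 1.34 ± 0.66 CPM at 48 h. By edgeR's quasi-likelihood test at an adjusted threshold of 0.05, 4742 genes rose and 4880 fell at 24 h, of which 1032 and 970 changed at least 2-fold. At 48 h 4722 rose and 4686 fell, 861 and 1010 of them at least 2-fold. Matrix, medium, time and collagenase digestion change together in these comparisons.

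Among single genes at 24 h, the largest rises were of FOSB, whose log2 fold change was 8.26 (SE 0.158, adjusted p = 2.03e-16 by edgeR's quasi-likelihood test), FOS at 7.18 (SE 0.138), KRTAP2-3, a hair keratin-associated protein gene, at 5.96 (SE 0.273) and ATF3, a stress-induced transcription factor, at 5.34 (SE 0.147). NR4A1, DUSP1 and the peptide hormone gene EDN1 rose by 4.63, 4.40 and 4.34. The largest falls were of F13A1, a coagulation factor subunit (-3.96, SE 0.281), RANBP3L (-3.69, SE 0.884), and the water channels AQP5 (-3.40) and AQP3 (-3.36). At 48 h the synaptic scaffold gene RIMS2 (4.601, SE 0.321), AOX1, an aldehyde oxidase (3.82, SE 0.101), and PDE1C, a cyclic nucleotide phosphodiesterase (3.73, SE 0.182), were among the largest rises. LTB (-4.33), the airway mucin gene MUC5B (-3.62) and CX3CL1 (-3.59) were among the largest falls. FOSB overlaps ERCC1 and AQP5 overlaps a noncoding gene. The host transcript MIR23AHG (4.82 at 24 h) overlaps ZSWIM4. Each overlap is on the opposite strand. The strand setting of the counting is not stated, so the values of these genes are uncertain.

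Of 35 gene lists fixed beforehand, 13 were called at 24 h and 21 at 48 h by camera with a preset correlation, and 7 and 6 of these calls held with an estimated correlation. At 24 h the immediate-early and dissociation list had 26 of 33 members higher and 2 lower (26 and 2 adjusted over the list alone; median log2 fold change 1.3, adjusted p = 2.17e-41 by camera on the edgeR fit, and 0.00124 with an estimated correlation). In the YAP-TAZ list 23 of 28 rose and 1 fell (23 and 1 adjusted over the list alone; median 0.65, adjusted p = 1.11e-18, and 0.00967 with an estimated correlation), led by CCN1 (3.46), CCN2 (3.37), F3 (2.01) and ANKRD1 (1.80). MRTF-SRF targets, the actin-regulated genes, rose in 19 of 27 and fell in 2 (20 and 2 adjusted over the list alone; median 0.34, adjusted p = 1.42e-06), led by FLNC (2.02) and TAGLN (1.82). ATF4 targets, the amino acid stress genes, rose in 19 of 33 and fell in 5 (22 and 6 adjusted over the list alone; median 0.46, adjusted p = 9.42e-09, and 0.00124 with an estimated correlation).

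All 41 DNA replication genes rose at 24 h (41 adjusted over the list alone; median 1.41, camera adjusted p = 5.41e-40 on the edgeR fit, but adjusted p = 0.0639 with an estimated correlation). MCM10 (1.99), CCNE2 (1.93), CDT1 (1.92) and E2F1 (1.84) rose most. Interferon-stimulated genes fell in 38 of 40 (39 adjusted over the list alone; median -1.06, adjusted p = 4.87e-31, and 0.0026 with an estimated correlation), led by OAS1 (-2.26) and OASL (-1.87). Antigen presentation genes fell in 22 of 23 and rose in 1 (the same adjusted over the list alone; median -0.795, adjusted p = 1.11e-13, but adjusted p = 0.111 with an estimated correlation), with HLA-DMB at -2.09 and HLA-DRA at -2.07. Endoplasmic reticulum chaperones of the unfolded protein response fell in 20 of 25 (20 adjusted over the list alone; median -0.46, adjusted p = 1.42e-06, but adjusted p = 0.188 with an estimated correlation). Polyadenylated replication-dependent histone transcripts fell in 10 of 19 and rose in 1 (the same adjusted over the list alone; median -0.93, adjusted p = 0.000616, and 0.0376 with an estimated correlation).

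**Figure D3:**
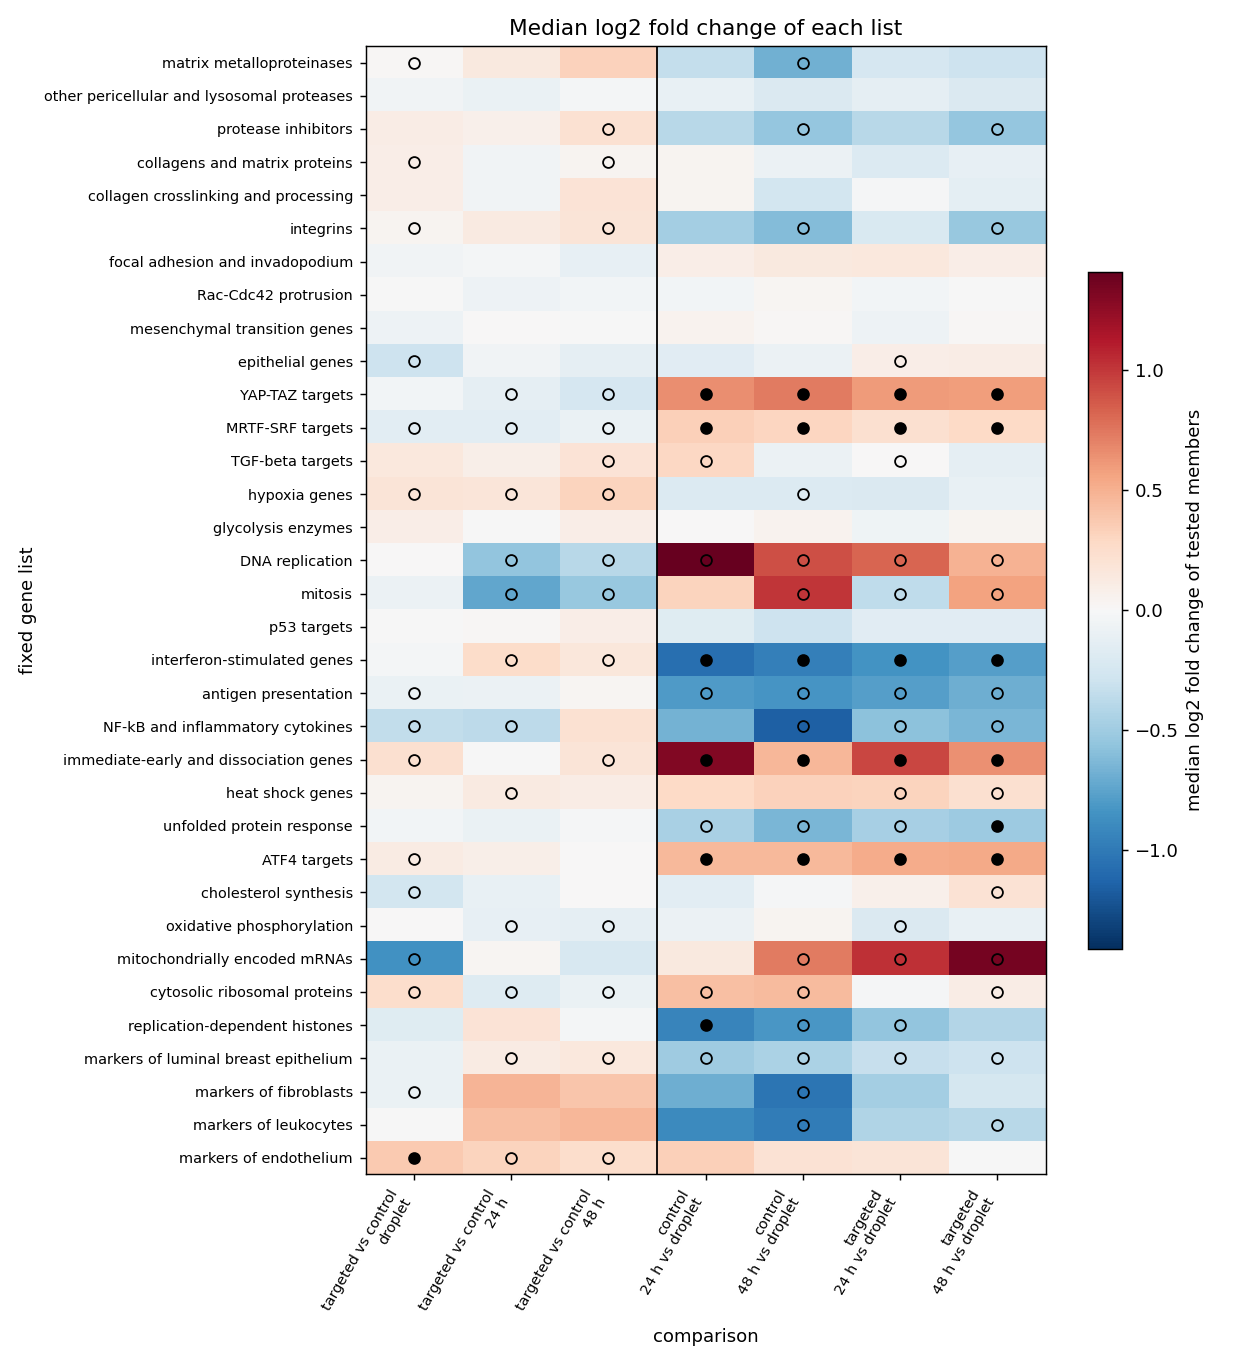
Median log2 fold change of the tested members of each of 34 fixed gene lists (rows) in 3 comparisons of targeted with control spheroids and 4 comparisons of collagen with droplets (columns); a circle marks an adjusted p under 0.05 by camera with the preset correlation, and a filled circle one that also held with an estimated correlation. In the genotype comparisons 1 circle is filled, for the endothelial marker list in droplets, and the DNA replication and mitosis lists are lower in targeted spheroids at 24 h and 48 h but not in droplets.

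Between 24 h and 48 h both collagen groups had been digested. In control spheroids 34 of 42 mitotic genes rose over this day, and 22 of 33 immediate-early, 31 of 41 replication and 16 of 38 matrix genes fell. The mitosis and replication list calls were lost with an estimated correlation. CCNB1, the mitotic cyclin, rose from 89.0 ± 8.18 to 304.0 ± 22.1 CPM (SD, n = 3 each), and ATF3 fell from 273.5 ± 35.5 to 51.8 ± 6.51 CPM. By edgeR's quasi-likelihood test 1077 genes rose and 1171 fell, 70 and 105 at least 2-fold, led by KIF20A (1.99), TMEM71 (1.88) and CCNB1 (1.77), with ATF3 (-2.40) and the chemokines CXCL3 (-2.20) and CXCL2 (-1.96) falling most. The total of 2248 became 1349 without control 24 h replicate 2, 1496 without control 48 h replicate 1 and 1446 without control 48 h replicate 2. KIF20A overlaps BRD8 and CDC23 on the opposite strand. Mitosis genes rose in 34 of 42 (38 adjusted over the list alone; median 0.76, camera adjusted p = 8.84e-51, but adjusted p = 0.0579 with an estimated correlation). Calls that held with an estimated correlation were the immediate-early list (22 of 33 lower and 3 higher; 25 and 3 adjusted over the list alone), TGF-beta targets (13 of 25 lower; 17 lower and 1 higher adjusted over the list alone), collagens and matrix proteins (16 of 38 lower and 1 higher; 17 and 1 adjusted over the list alone) and matrix metalloproteinases (5 of 14 lower; 6 adjusted over the list alone). Replication genes fell in 31 of 41 (33 adjusted over the list alone; median -0.51, adjusted p = 1e-31, but adjusted p = 0.096 with an estimated correlation).

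**Figure D4:**
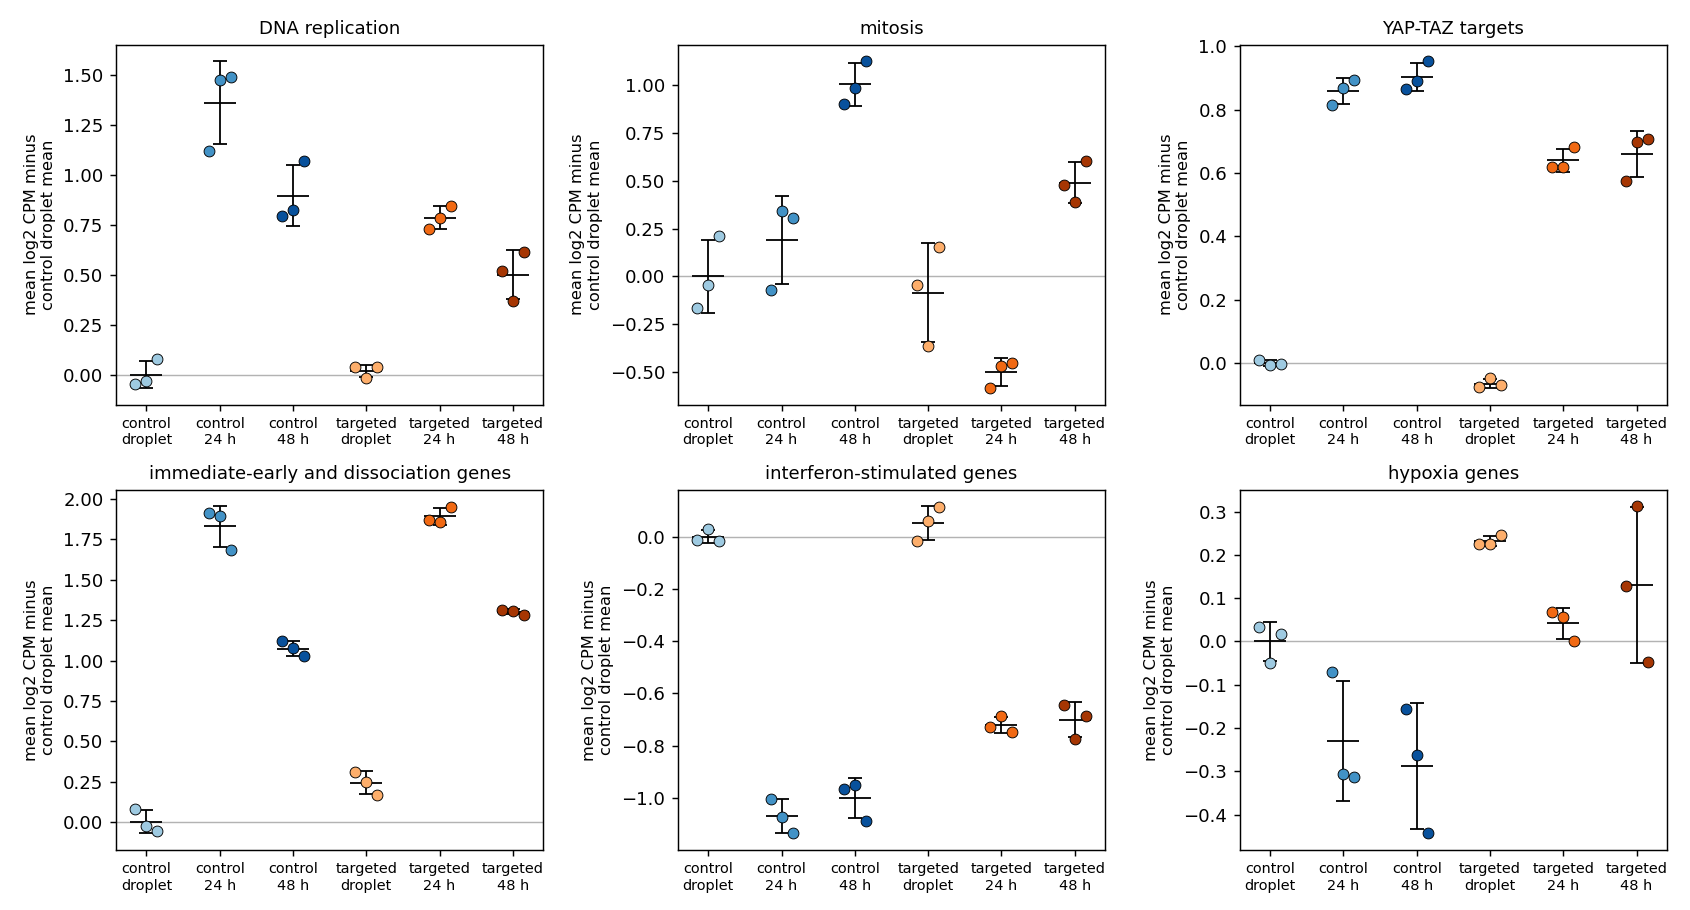
Mean log2 CPM of the tested members of 6 fixed gene lists in each library, minus the mean of the control droplet libraries; points are libraries, the long horizontal mark is the group mean and the whiskers are 1 SD (n = 3). For DNA replication the control 24 h libraries lie at 1.12 to 1.49 and the targeted 24 h libraries at 0.73 to 0.85, while the droplet libraries of both genotypes lie between -0.05 and 0.08.

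Targeted and control spheroids, labelled MMP14-KO and Wildtype, were compared first in droplets, before contact with collagen. The labels do not state whether the targeted cells are a single clone or a pool. In every comparison of genotypes, MMP14 loss therefore cannot be told apart from other differences between the cell populations. In targeted spheroids 13 of 13 mitochondrially encoded mRNAs, 14 of 29 cholesterol synthesis genes and 13 of 27 actin-regulated genes were lower. Higher were 45 of 73 ribosomal protein, 16 of 38 hypoxia and 11 of 33 immediate-early genes. Each of these 6 list calls was lost with an estimated correlation. No shift of DNA replication genes was detected (camera adjusted p = 0.759 on the edgeR fit). AQP1, a water channel gene, was at 19.4 ± 3.19 CPM in control and 4.55 ± 0.72 CPM in targeted droplets (SD, n = 3 each). TIE1, an endothelial receptor kinase gene, was at 0.987 ± 0.206 and 9.82 ± 0.752 CPM. By edgeR's quasi-likelihood test 1312 genes were higher and 1652 lower in targeted spheroids, 331 and 164 of them at least 2-fold. The total of 2964 fell to 1959 without control droplet replicate 2. Mitochondrially encoded transcripts made up 2.10 to 2.65% of counts in control droplets and 0.971 to 1.74% in targeted droplets.

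Genes that differed in droplets included LDLRAD4, an inhibitor of TGF-beta signalling, at 7.73 ± 0.73 CPM in targeted and 0.165 ± 0.0635 CPM in control spheroids, OLFML1 at 8.99 ± 1.12 and 0.241 ± 0.162 CPM, and LBP, a lipopolysaccharide-binding protein gene, at 14.7 ± 4.21 and 1.35 ± 0.831 CPM (SD, n = 3 each). OLFML1 overlaps a noncoding gene on the opposite strand. RFPL4A and RFPL4AL1 were also higher, with log2 fold changes of 5.11 and 5.31 averaged over the 3 conditions, but they are near-identical neighbours and reads could be split between them. COL1A2, a chain of type I collagen, was lower at 0.848 ± 0.146 against 6.32 ± 1.58 CPM, as was the galectin gene LGALS12 at 1.61 ± 0.223 against 9.09 ± 1.46 CPM. RAB17 (-2.16, SE 0.431), AQP5 (-2.14, SE 0.299) and ALPP, a placental phosphatase gene (-2.004, SE 0.299), fell as well.

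Of the 35 lists, 16 were called in droplets with the preset correlation, and only the endothelial marker list, with 3 of 6 members higher and 1 lower (the same adjusted over the list alone), held with an estimated correlation (adjusted p = 0.0432 by camera on the edgeR fit). Mitochondrially encoded mRNAs were lower in 13 of 13 (13 adjusted over the list alone; median -0.85, adjusted p = 3.22e-09, but adjusted p = 0.266 with an estimated correlation). Cholesterol synthesis genes were lower in 14 of 29 (18 adjusted over the list alone; median -0.255, adjusted p = 1.53e-07, but adjusted p = 0.266 with an estimated correlation), among them SC5D (-0.65) and DHCR7 (-0.65). Ribosomal protein genes were higher in 45 of 73 (55 adjusted over the list alone; median 0.24, adjusted p = 7.88e-14, but adjusted p = 0.413 with an estimated correlation). In collagen none was higher: 35 were lower at 24 h (41 adjusted over the list alone; median -0.185, adjusted p = 4.65e-08, but adjusted p = 0.728 with an estimated correlation) and 10 at 48 h (6 adjusted over the list alone; median -0.0985, adjusted p = 0.00335, but adjusted p = 0.735 with an estimated correlation, and 0.224 without targeted 48 h replicate 2). MRTF-SRF targets were lower in 13 of 27 (14 lower and 1 higher adjusted over the list alone; median -0.15, adjusted p = 9.83e-05, but adjusted p = 0.155 with an estimated correlation), with the myosin light chain gene MYL9 at -0.71 and CNN2 at -0.57. Epithelial genes were lower in 13 of 30 and higher in 2 (14 and 2 adjusted over the list alone; median -0.29, adjusted p = 0.000209, but adjusted p = 0.11 with an estimated correlation), with ESRP2 at -2.11 and MUC1 at -1.61. Hypoxia genes were higher in 16 of 38 (20 adjusted over the list alone; median 0.185, adjusted p = 3.41e-05, but adjusted p = 0.506 with an estimated correlation). Immediate-early genes were higher in 11 of 33 (14 adjusted over the list alone; median 0.227, adjusted p = 9.83e-05, but adjusted p = 0.266 with an estimated correlation). In the matrix metalloproteinase list MMP9 (2.17), MMP10 (1.43) and MMP1 (0.85) were higher and 2 members, MMP14 among them, were lower (the same adjusted over the list alone). Its median of 0.018 and mean of 0.057 were positive while the test, at adjusted p = 0.0469, pointed down. That call too was lost (adjusted p = 0.199 with an estimated correlation, and 0.0591, 0.0606 and 0.0733 without targeted droplet replicates 1, 2 and 3).

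In collagen at 24 h, 40 of 41 replication genes, 41 of 42 mitotic genes and 13 of 28 YAP-TAZ targets were lower in targeted than control spheroids, and 20 of 40 interferon-stimulated and 12 of 38 hypoxia genes were higher. Each of these list calls was lost with an estimated correlation, at 24 h and at 48 h. MKI67, a proliferation marker, differed at 24 h by a log2 fold change of -0.96 (SE 0.152, edgeR's quasi-likelihood test, adjusted p = 0.000437). AXL, a receptor kinase and YAP target, differed by -0.68 (SE 0.0595) at 24 h and -0.76 (SE 0.0596) at 48 h. OAS1, an antiviral sensor, differed by 2.68 (SE 0.149) and 2.60 (SE 0.147). At 24 h 2328 genes were higher and 2682 lower, of which 540 and 96 differed at least 2-fold, and at 48 h 2458 were higher and 2571 lower, 591 and 107 of them at least 2-fold. With scaling by library size alone, the share of calls that were higher moved from 46.5% to 61.9% at 24 h and from 48.9% to 64.3% at 48 h. Targeted libraries in collagen held more long noncoding RNA (1.06 to 1.16% of counts, against 0.945 to 1.00% in control), and genes under 2 CPM had a median log2 fold change of 0.235 at 24 h and 0.23 at 48 h.

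DNA replication genes were lower at 24 h in 40 of 41 (40 adjusted over the list alone; median -0.56, camera adjusted p = 1.56e-26 on the edgeR fit, but adjusted p = 0.254 with an estimated correlation) and at 48 h in 32 of 41 (35 adjusted over the list alone; median -0.39, adjusted p = 1.45e-12, but adjusted p = 0.367 with an estimated correlation). RRM2, a ribonucleotide reductase subunit (-1.13 at 24 h), and CCNE2, a G1/S cyclin (-0.95), led the list. Mitosis genes were lower at 24 h in 41 of 42 (41 adjusted over the list alone; median -0.73, adjusted p = 6.28e-20, but adjusted p = 0.368 with an estimated correlation) and at 48 h in 35 of 42 (39 adjusted over the list alone; median -0.54, adjusted p = 4.94e-12, but adjusted p = 0.428 with an estimated correlation). Of the YAP-TAZ targets 13 of 28 were lower and 1 higher at 24 h (14 and 1 adjusted over the list alone; median -0.13, adjusted p = 0.000348, but adjusted p = 0.368 with an estimated correlation). At 48 h 18 were lower and 1 higher (19 and 2 adjusted over the list alone; median -0.24, adjusted p = 7.71e-07, but adjusted p = 0.268 with an estimated correlation), with ANKRD1 at -0.78.

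Interferon-stimulated genes were higher at 24 h in 20 of 40 (25 higher and 1 lower adjusted over the list alone; median 0.255, camera adjusted p = 4.65e-08 on the edgeR fit, but adjusted p = 0.254 with an estimated correlation), with OASL at 1.17 and MX2 at 0.91. At 48 h 16 were higher and 3 lower (18 and 3 adjusted over the list alone; median 0.158, adjusted p = 3.35e-05, but adjusted p = 0.36 with an estimated correlation). Hypoxia genes were higher in 12 of 38 and lower in 1 at 24 h (the same adjusted over the list alone; median 0.17, adjusted p = 0.000416, but adjusted p = 0.728 with an estimated correlation). At 48 h they were higher in 22 and lower in 1 (31 and 1 adjusted over the list alone; median 0.32, adjusted p = 4.75e-09, but adjusted p = 0.367 with an estimated correlation), including NDRG1 (1.45) and CA9 (0.86). Collagens and matrix proteins were higher in 11 of 38 and lower in 5 at 48 h (12 and 6 adjusted over the list alone; median 0.04, adjusted p = 0.00335, but adjusted p = 0.268 with an estimated correlation), with SPARC (2.40), LAMA4 (2.35) and COL6A2 (2.27) higher and COL1A2 (-3.22) lower. Integrins were higher in 6 of 16 and lower in 2 (7 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.00832, but adjusted p = 0.367 with an estimated correlation), with ITGA7, a laminin receptor subunit, at 3.30 (SE 0.301) and ITGB3 at 1.01 (SE 0.0887). Inflammatory NF-kB genes were lower in 11 of 39 and higher in 2 at 24 h (12 and 2 adjusted over the list alone; median -0.37, adjusted p = 0.0247, but adjusted p = 0.796 with an estimated correlation), among them the acute-phase genes SAA1 (-1.84) and SAA2 (-1.93), which are close paralogs (SAA2 also overlaps the readthrough gene SAA2-SAA4), and the cytokine gene CSF3 (-1.76). This call rests on control 24 h replicate 1, whose mean over the list was -0.004708 relative to control droplets, against -0.7777 and -0.7858 in the other control 24 h libraries and -0.9946 to -0.6877 in targeted ones. Without that library the adjusted p was 0.613, and without targeted 24 h replicate 3 it was 0.0997. SAA1, SAA2 and CSF3 passed without control 24 h replicate 1 at -1.399, -1.467 and -1.136. At 48 h 6 NF-kB genes were higher and 5 lower (the same adjusted over the list alone; median 0.219, adjusted p = 0.361 by camera).

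Single genes that differed most in collagen included NDRG2, at 5.21 ± 0.291 CPM in targeted and 0.226 ± 0.134 CPM in control spheroids at 24 h, and the adhesion receptor gene ADGRL3 at 10.1 ± 0.445 and 0.603 ± 0.219 CPM (SD, n = 3 each). SEL1L3 stood at 6.66 ± 2.45 and 0.399 ± 0.0574 CPM at 48 h. NDRG2 overlaps ARHGEF40 and SEL1L3 overlaps SMIM20 on the opposite strand. Lower in targeted spheroids at 48 h were SORL1, a sorting receptor gene (5.08 ± 0.343 against 17.8 ± 0.741 CPM), the oxytocin receptor gene OXTR (2.76 ± 0.41 against 6.92 ± 0.776 CPM) and the receptor kinase gene MUSK (4.70 ± 0.607 against 10.9 ± 0.561 CPM).

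Averaged over the 3 conditions, 3601 genes were higher and 3934 lower in targeted spheroids by edgeR's quasi-likelihood test, 492 and 103 at least 2-fold. With scaling by library size alone, 61.1% of the calls were higher, against 47.8%. In all 3 conditions 618 genes were higher and 640 lower, against 25.9 and 39.3 for independent lists. Of these, 211 higher and 31 lower genes differed at least 2-fold in each. Another 32 genes were called in all 3 with mixed direction. Across genes, which are not independent replicates, the targeted-to-control log2 fold changes correlated between 24 h and 48 h with Pearson's r of 0.685 and a Spearman coefficient of 0.69. Between droplets and 24 h they correlated with r of 0.518 and a Spearman coefficient of 0.359, and between droplets and 48 h with 0.51 and 0.367. These 3 comparisons share no library.

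Averaged over conditions, 15 of the 35 lists were called with the preset correlation and 0 with an estimated one. The lists not called included focal adhesion and invadopodium genes (5 of 45 higher and 19 lower, as adjusted over the list alone; adjusted p = 0.091 by camera on the edgeR fit), Rac-Cdc42 protrusion genes (7 of 42 higher and 20 lower, as adjusted over the list alone; adjusted p = 0.387, with a mean of 0.20 against a median of -0.08) and mesenchymal transition genes (8 of 27 higher and 8 lower, as adjusted over the list alone; adjusted p = 0.422, with a mean of -0.11 against a median of 0.01). Glycolysis enzymes (7 of 20 higher, 2 lower), p53 targets (9 of 25 higher, 9 lower; 10 higher and 9 lower adjusted over the list alone), collagen crosslinking and processing genes (8 of 21 higher, 4 lower; 9 higher and 4 lower adjusted over the list alone), other pericellular and lysosomal proteases (8 of 33 higher, 11 lower) and protease inhibitors (13 of 25 higher, 6 lower) had adjusted p of 0.298, 0.586, 0.318, 0.646 and 0.28. Heat shock genes (10 of 21 higher, 2 lower) and oxidative phosphorylation genes (2 of 49 higher, 20 lower) were called at adjusted p = 0.0454 and 0.0168, and these calls were lost (adjusted p = 0.448 and 0.701 with an estimated correlation). Heat shock genes were also lost without control 24 h replicate 1 (0.0716), control 48 h replicate 1 (0.0711), targeted 24 h replicate 3 (0.0611) and targeted 48 h replicates 1 and 3 (0.0714 and 0.0646). Oxidative phosphorylation genes were lost without targeted 48 h replicate 2 (0.0517). Markers of luminal epithelium (6 of 14 higher, 5 lower), fibroblasts (4 of 9 higher, 3 lower) and leukocytes (5 of 8 higher, 1 lower) had adjusted p of 0.0557, 0.778 and 0.262. The luminal list was called at 24 h (4 higher, 2 lower; 5 and 2 adjusted over the list alone; median 0.112, camera adjusted p = 0.0321, but adjusted p = 0.368 with an estimated correlation). It was also called at 48 h (6 higher, 3 lower; 6 and 4 adjusted over the list alone; median 0.153, adjusted p = 0.0416, but adjusted p = 0.367 with an estimated correlation). The call was lost at 24 h without control replicate 3 (0.0592) or targeted replicate 1 (0.0875). At 48 h it was lost without control replicate 3 (0.0879) or targeted replicate 1 (0.0644). Fibroblast markers were called in droplets (1 of 9 higher, 3 lower; adjusted p = 0.0486 by camera, but adjusted p = 0.199 with an estimated correlation). This call was lost without control droplet replicate 3 (0.0509) or targeted droplet replicate 1 (0.0829). Endothelial markers were called at 24 h (3 of 6 higher, 2 lower; median 0.315, adjusted p = 0.00358 by camera), at 48 h (3 higher, 1 lower; median 0.246, adjusted p = 0.00977) and on average (3 higher, 1 lower; median 0.343, adjusted p = 0.000454). Each call was lost with an estimated correlation (adjusted p = 0.0983, 0.191 and 0.0641).

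Targeted spheroids also responded to collagen. FOSB, FOS and KRTAP2-3 were again among the largest rises, with log2 fold changes of 8.39, 6.65 and 5.14 at 24 h. MUC5B fell from 21.8 ± 4.41 CPM in droplets to 1.68 ± 0.614 CPM at 24 h, and the nodal antagonist gene LEFTY1 from 15.0 ± 3.02 to 2.01 ± 0.346 CPM (SD, n = 3 each). By edgeR's quasi-likelihood test 4335 genes rose and 4370 fell at 24 h, 1070 and 554 at least 2-fold, and 4399 rose and 4018 fell at 48 h, 912 and 557 at least 2-fold. Between 24 h and 48 h 353 rose and 295 fell, 43 and 27 at least 2-fold, for a total of 648. It became 373, 324 and 342 without targeted 24 h replicates 1, 2 and 3, and 400 without targeted 48 h replicate 3. With scaling by library size alone, the share that rose over this day was 44.2% in place of 54.5%. Mitosis genes fell in 21 of 42 at 24 h (21 adjusted over the list alone; median -0.36, camera adjusted p = 0.000538, but adjusted p = 0.651 with an estimated correlation) and rose in 39 of 42 between 24 h and 48 h (42 adjusted over the list alone; median 0.92, adjusted p = 8.2e-116, and 0.0066 with an estimated correlation).

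Whether the response to collagen differed between the genotypes was tested with an interaction term. The rise of CCN2 was smaller in targeted spheroids, where it reached 658.6 ± 69.2 CPM at 24 h from 117.8 ± 3.06 CPM in droplets (SD, n = 3 each). The rise was also smaller for 32 of 41 replication genes at 24 h, and 11 of 40 interferon-stimulated genes responded more positively, but both list calls were lost with an estimated correlation (adjusted p = 0.17 each by camera on the edgeR fit). By edgeR's quasi-likelihood test 1262 genes differed in their response at 24 h (565 more positive and 697 more negative in targeted spheroids, 106 and 26 by at least 2-fold) and 1156 at 48 h (682 and 474, 138 and 16 by at least 2-fold). With scaling by library size alone, 59% and 73.9% were more positive, against 44.8% and 59%. Single libraries moved these counts. At 24 h the count became 473 and 624 without control droplet replicates 1 and 2, 619 without targeted droplet replicate 3, 1953, 601 and 414 without control 24 h replicates 1, 2 and 3, and 639 and 738 without targeted 24 h replicates 1 and 2. At 48 h it became 316, 458 and 1977 without control droplet replicates 1, 2 and 3, 707 and 394 without targeted droplet replicates 1 and 3, and 764 and 337 without control 48 h replicates 2 and 3. For the difference between genotypes in the change from 24 h to 48 h, 0 genes passed edgeR's test, with 1107 at an unadjusted p under 0.05. DESeq2 called 5, limma-voom 0, and edgeR 240 with no filter on low counts and 2 without control 24 h replicate 1.

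Genes with the smallest adjusted p in the interaction at 24 h were G0S2, a lipolysis inhibitor gene (-1.17, SE 0.126), the Wnt receptor gene FZD8 (-0.91, SE 0.114), CCN2 (-0.89, SE 0.112), TACC2 (0.74, SE 0.0971) and PDGFRB (1.06, SE 0.142), with adjusted p = 0.000438 for each by edgeR's quasi-likelihood test. At 48 h NEDD9, an adhesion scaffold gene (0.94, SE 0.101), TRIML2 (1.19, SE 0.135) and BMF, an apoptosis activator gene (1.16, SE 0.137), responded more positively and PLAC8 (-0.86, SE 0.101) and the metallothionein gene MT2A (-0.84, SE 0.11) more negatively. Of the replication genes 32 of 41 responded more negatively at 24 h (39 adjusted over the list alone; median -0.55, camera adjusted p = 7.77e-35, but adjusted p = 0.17 with an estimated correlation), and of the ribosomal protein genes 55 of 73 (72 adjusted over the list alone; median -0.405, adjusted p = 1.61e-46, but adjusted p = 0.17 with an estimated correlation). Interferon-stimulated genes responded more positively in 11 of 40 (17 adjusted over the list alone; median 0.305, adjusted p = 7.93e-10, but adjusted p = 0.17 with an estimated correlation).

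The responses of the genotypes were also compared without shared libraries. Across genes, the log2 fold changes of targeted and control spheroids correlated with Pearson's r of 0.683 at 24 h and 0.666 at 48 h. At 24 h 3348 genes rose in both genotypes and 3459 fell in both, against 1210 and 1250 for independent lists, and 53 moved in opposite directions. In control spheroids 861 genes rose and 1010 fell at least 2-fold by 48 h. Of those that rose, 261 were lower and 41 higher in targeted than control spheroids at 24 h (median -0.21, camera adjusted p = 4.24e-07 on the edgeR fit, but adjusted p = 0.0963 with an estimated correlation). Of those that fell, 343 were higher and 50 lower (median 0.385, camera adjusted p = 3.56e-12, but adjusted p = 0.0748 with an estimated correlation). These set tests are not matched for level, and genes under 2 CPM also had medians above 0 between genotypes (0.235 at 24 h and 0.23 at 48 h). Sets defined at 24 h and tested at 48 h gave a median of -0.125 for 1032 genes that rose (adjusted p = 0.00291, but adjusted p = 0.275 with an estimated correlation) and 0.46 for 970 that fell (adjusted p = 1.35e-12, but adjusted p = 0.0748 with an estimated correlation). With sets at 4-fold only the 234 genes that fell at 24 h held with an estimated correlation (median 0.811 at 48 h, adjusted p = 0.0164 by camera on the edgeR fit). With the replicate number as a block, both sets defined at 48 h and the genes that fell at 24 h held with an estimated correlation (adjusted p = 0.0283, 0.0136 and 0.0136 by camera), and the genes that rose at 24 h did not (0.203).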

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

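The tests with expression-matched lists, of the 2 lists in droplets, of olfactory receptor genes, of nuclear RNAs and of luminal markers were chosen only after the result was seen. A test of the difference between the genotypes' responses to collagen, an interaction term, picked the replication and mitosis lists and the values in the last 2 paragraphs, while the low-abundance RNAs and the set of 242 genes come from the comparisons of genotypes. The test called 1262 genes at 24 h and 1156 at 48 h.

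The replication and mitosis lists had interaction medians of -0.551 and -0.671 at 24 h and -0.414 and -0.449 at 48 h. The 83 genes in either list had a median of -0.672 between genotypes at 24 h (interquartile range -0.784 to -0.537). Of 10000 expression-matched random lists the lowest lay at -0.137, and the median over these lists was -0.0417. This argues against a shift of all abundant mRNAs as the whole cause. Because the same libraries also picked the lists, their rank among random lists does not measure chance. With the trend on GC content and transcript length removed the median of the 83 genes was -0.741 (-0.861 to -0.601), which argues against that bias as the whole cause. In droplets the median was -0.0344 (-0.151 to 0.0739) and at 48 h it was -0.481, so these genes as a set were not lower in every condition. The interaction that picked the lists favours a droplet value unlike that in collagen. The droplet value therefore cannot decide on a growth difference of the targeted cells. That a weaker entry into the cell cycle inside collagen underlies the pattern is a hypothesis that was not tested. MMP14 loss and any other difference between the cell populations are both open. The labels do not state whether the targeted cells are a single clone or a pool. The list calls were also lost with an estimated correlation.

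Low-abundance RNAs tended to be higher in targeted spheroids in collagen. At 24 h the 4184 genes under 2 CPM had a median log2 fold change of 0.235, with 490 called higher and 101 lower. The gain per gene of 404 olfactory receptor genes was 0.0096 of the gain per low-abundance gene at 24 h (upper limit 0.0585) and -0.0127 at 48 h, which argues against genomic DNA. With every library thinned to the total of the smallest, the median was 0.234 at 24 h and 0.24 at 48 h. Thinning keeps each gene's expected share of its library, and the same genes were tested. The median was therefore bound to change little, and this test cannot decide on unequal depth. More nuclear RNA in these libraries cannot be told apart from a change in transcription: MALAT1 and NEAT1 were between 0.517 and 1.37 higher at 24 h and 48 h, and only MALAT1 at 48 h passed (adjusted p = 0.00164 by edgeR's quasi-likelihood test). In droplets they were at -0.358 and -0.651, with adjusted p = 0.394 and 0.107.

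A set of 242 genes, 211 higher and 31 lower, differed at least 2-fold in the same direction in all 3 conditions. Over the 232 with a position, the median signed change of the 10 flanking genes was 0.0381 (interquartile range -0.0315 to 0.119), which argues against copy number as the cause for the set, but not for 25 genes (10.8%) whose flanking genes moved by 0.3 or more, against 1.5% of random genes. The median fall of the 31 lower genes would need other cells at 79.2% of the culture, while the luminal markers CDH1 and GATA3 rose by at most 0.608 and 0.106 (log2 fold change plus 2 SE), which argues against admixture of luminal breast cells as the cause of the lower genes. As the source of the 211 higher genes a small share of such cells cannot be told apart from a change within the line, since of the 3 markers named for the test ESR1 was too low to be tested: CDH1 and GATA3 had a median of 0.0309, while FOXA1 rose from 0.0215 ± 0.0278 to 0.315 ± 0.171 CPM (SD, n = 9), and control spheroids express 12 of the 16 luminal markers at a mean of at least 1 CPM. A difference between cell populations that arose before or during targeting may explain such constant differences as well as MMP14 loss, and the labels do not state whether the targeted cells are a single clone or a pool.

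The same interaction test gave these other values as log2 differences of the response, targeted minus control. At 24 h they were -1.17 for G0S2, -0.91 for FZD8, -0.89 for CCN2, 0.74 for TACC2, 1.01 for TRIML2, 0.79 for SLC38A4, 1.06 for PDGFRB and -0.83 for MT2A. At 48 h they were 0.94 for NEDD9, 1.19 for TRIML2, -1.18 for G0S2, -0.86 for PLAC8, -0.79 for CDCA7L, 1.16 for BMF, -0.90 for CCN2 and -0.84 for MT2A. SLC38A4 and CDCA7L overlap genes on the opposite strand. List medians at 24 h and 48 h were 0.31 and 0.25 for epithelial genes, -0.119 and -0.138 for YAP-TAZ targets, 0.305 and 0.203 for interferon-stimulated genes, -0.042 and -0.0865 for ATF4 targets, 0.199 and 0.225 for cholesterol synthesis, -0.133 and -0.126 for oxidative phosphorylation, 0.917 and 0.651 for mitochondrially encoded mRNAs, -0.405 and -0.314 for ribosomal proteins and 0.377 and 0.331 for histones. Each of these list calls was lost with an estimated correlation.

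The interaction counts were also set against 60 draws that reassign genotype labels within conditions. As many genes were reached in 2 of the 60 draws at 24 h and in 2 at 48 h, the real labels included, a share under 0.05. Draws that mix the genotypes within a group also carry the genotype differences into the spread within groups. The share therefore cannot decide whether the response to collagen differed between the genotypes. The highest other draws called 1736 and 1288 genes, above the real counts of 1262 and 1156, and the median of the others was 0. By construction, exchanging all genotype labels in a condition turns the difference of the genotype effects into their sum, and which draws gave the highest counts was not recorded.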

How the results depend on the processing

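Only the counts restricted to genes with a mean of at least 10 CPM were chosen after the result was seen. Leaving out a library leaves 2 in its group, which are assumed to vary like the other groups. Only gene values and list calls past the threshold in the main fit were followed, which makes a reversal unlikely from the start. Over the gene values named, 24529 comparisons with an alternative kept direction and side of the threshold, 1613 lost the threshold and 0 reversed. Over the list calls the numbers were 2422, 400 and 1. The reversed one is the hypoxia list between 24 h and 48 h in targeted spheroids, with adjusted p = 0.0485 by camera and 0.64 in the other direction without MMP14KO 48 h replicate 2. Over its alternatives it ranged from 2.92e-06 without MMP14KO 48 h replicate 3 to 0.744 with an estimated correlation. For each change below the cause was not tested, unless stated.

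With no filter on low counts, which tests more genes, the counts were 1101 for targeted 48 h against 24 h, 2046 and 2110 for the interactions at 24 h and 48 h, and 240 for the interaction between 24 h and 48 h. DESeq2 gave 1758 for the interaction at 48 h and 5 for that between 24 h and 48 h. The labels do not state whether libraries with the same replicate number were handled together. Over 45 pairs with the same number, residual correlations were -0.07 to 0.14 (median 0.0075). Outside their group, 10 of 18 libraries correlated best with their own number, so a pairing by number is neither shown nor excluded. With the replicate number as a block the interactions at 24 h and 48 h gave 1782 and 1838 genes. No count fell, and all but that at 48 h stayed within 1.5 times. The block also brought 3 of the 4 collagen-response sets under 0.05 with an estimated correlation (adjusted p = 0.0283, 0.0136 and 0.0136, with 0.203 for the genes that rose at 24 h).

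With an estimated correlation, camera called 1 list in droplets, 0 at 24 h, 0 at 48 h and 0 on average between genotypes. It called 7 in control 24 h and 6 in control 48 h against droplets, 4 in control 48 h against 24 h, 5 and 7 in targeted 24 h and 48 h against droplets, 3 in targeted 48 h against 24 h, and 0 in each of the 3 interactions. The collagen-response sets had adjusted p of 0.0963 and 0.0748 (rose and fell by 48 h) and 0.275 and 0.0748 (by 24 h) by camera on the edgeR fit. At 4-fold the sets by 48 h had medians of -0.213 and 0.571 (adjusted p = 0.156 and 0.0506 with an estimated correlation by camera) and those by 24 h -0.141 and 0.811 (adjusted p = 0.191 and 0.0164), so only the genes that fell by 24 h held. Fry called 27 lists on average between genotypes, 26 in control 24 h, 28 in targeted 24 h and 31 in targeted 48 h against droplets, 5 in targeted 48 h against 24 h, 11 in the interaction at 48 h and 0 in that between 24 h and 48 h. Among genes with a mean of at least 10 CPM, Pearson's r across genes rose to 0.863 between genotype effects at 24 h and 48 h, and between genotypes' collagen responses to 0.891 at 24 h, 0.888 at 48 h and 0.766 between these times. That set called 2285, 3833, 3616 and 5228 genes between genotypes in droplets, at 24 h, at 48 h and on average, and 1375 and 1206 in the interactions.

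Without 1 library, the count ranged from 1959 (without control droplet replicate 2) to 2949 between genotypes in droplets, 1349 (without control 24 h replicate 2) to 2027 in control 48 h against 24 h, and 324 (without MMP14KO 24 h replicate 2) to 854 in targeted 48 h against 24 h. The interactions ranged from 414 to 1953 at 24 h (without control 24 h replicates 3 and 1), 316 to 1977 at 48 h (without control droplet replicates 1 and 3) and 0 to 2 between 24 h and 48 h (2 without control 24 h replicate 1, which also lowered the lists called there from 20 to 8). Other counts stayed within 1.5 times, such as 3408 to 5035 between genotypes at 24 h, 3571 to 4643 at 48 h and 6974 to 7710 on average. MMP14 stayed between -3.553 and -3.501 on average. At these depths genes of few counts are not tested, and fold changes near 1.5 are missed more often than larger ones in simulated data.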

Other observations

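The splits of the libraries in this part were planned, and the gene values in its last paragraph were chosen after they were seen.

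For each comparison of a pair of groups, 3 libraries against 3 make 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, reached the real count. The real count and the highest of the other splits were 2964 and 5 between genotypes in droplets, 5010 and 0 at 24 h, and 5029 and 2 at 48 h. They were 9622 and 0 in control 24 h against droplets, 9408 and 0 in control 48 h against droplets, and 2248 and 97 in control 48 h against 24 h. In targeted spheroids they were 8705 and 0 at 24 h against droplets, 8417 and 0 at 48 h against droplets, and 648 and 0 at 48 h against 24 h. For the genotype difference averaged over conditions, 1 of 60 draws, the real one, reached 7535 genes, and the highest other draw called 14. Splits and draws that mix groups carry the group differences into the spread within groups, so low counts in them were likely from the start. The share under 0.05 for the averaged difference speaks only against labels given to these libraries at random. A chance difference between cultures is not excluded, since the labels do not state whether replicates are separate cultures. For the interaction between 24 h and 48 h all 60 draws reached the real count of 0. Another draw called 3973. Which draw this was is not recorded, and why it lies above the real count was not tested.

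Mitochondrially encoded transcripts made up 2.46 ± 0.307% of counts in control droplets and 1.41 ± 0.395% in targeted droplets (SD, n = 3 each). In collagen the shares were 2.55% and 2.83% at 24 h and 3.67% and 3.36% at 48 h. MT-ND2 differed between genotypes in droplets by a log2 fold change of -1.09 (SE 0.188) and MT-ND1 by -1.04. Of 1958 long noncoding RNAs tested, those that differed at least 2-fold between genotypes were 47 higher and 18 lower in droplets, 104 and 8 at 24 h and 98 and 11 at 48 h. More protein-coding genes were higher than lower too. Of 13609 tested they were 261 and 131 in droplets, 387 and 79 at 24 h and 436 and 83 at 48 h.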
